A study of Mus musculus with 6 samples.

How the data were processed

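Small RNA libraries were prepared from total RNA of N2a cells, a mouse neuroblastoma line, that had been differentiated with retinoic acid and then given RSL3 or its solvent DMSO. Each group had 3 libraries. Per the labels, adapters were joined to both RNA ends, the cDNA was amplified, fragments matching RNAs of 15 to 35 nt were selected, and 50 cycles were run on an Illumina sequencer. Per the submitters' processing notes, the tools were cutadapt, Bowtie and edgeR, and the genome build was GRCm38. Their order, versions and settings, the miRNA annotation release and the treatment of reads that match several miRNAs are not given in the sources used here.

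The deposited tables hold a normalised signal per mature miRNA, which the authors named CPM. The same 685 mature miRNAs were listed in all 6 libraries. The values did not sum to the fixed total of a plain CPM: the sums per library ran from 949375 to 1068890 and were above that total in 3 libraries. Every value was a whole multiple of 1 step per library, so the read numbers were recovered by dividing by that step, and 100% of the values came out whole within 0.01. The sum of the recovered reads times a TMM factor (edgeR's library scaling factor) computed from those same reads gave the divisor of each library, with TMM factors from 0.936 to 1.05. The deposited signal was therefore TMM-scaled CPM over the listed miRNAs, whereas plain CPM had been assumed before the data were examined. Reads of other small RNAs are not analysed here, so a change in the total amount of miRNA per cell would not be seen.

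The listed miRNAs held 6058006, 4306460 and 5248668 reads in DMSO libraries 1 to 3 and 3924599, 3406276 and 4989380 reads in RSL3 libraries 1 to 3. These totals are sums over entries, so reads that entries share are counted more than once. A single read was worth 0.157 to 0.314 CPM, and 3 reads, the upper limit that a count of 0 allows, 0.470 to 0.941 CPM. This limit covers counting error only. The labels do not say whether the replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Replicate libraries differed by much more than counting noise, with a chi-square per degree of freedom of 83.8 to 296 over the pairs within a group, so no library was treated as a copy of another.

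The design, the lists and the alternatives were fixed before the data were examined. The tests used R 4.3.3 with limma 3.58.1 on log2(CPM + 1), with a mean-variance trend in the moderated variances, a two-sided test and Benjamini-Hochberg adjustment at 0.05. A miRNA was tested when its CPM reached 1 in at least 3 libraries, which left 666 and set aside 19. Fold changes are on the log2(CPM + 1) scale, which understates the change of low miRNAs. For the arm ratio, log2((CPM of 5p + 1)/(CPM of 3p + 1)) was tested with limma for 182 precursors with both arms above the same filter. A set of 18 lists of miRNA names was written from general knowledge, and both arms of a named precursor were members. Lists with at least 5 tested members were compared with the other miRNAs by camera. It used a preset correlation of 0.01, and then an estimated correlation. Fry tested each list on its own, with a directional test and a mixed test that allows members to move in opposite directions. Summed CPM of a list was compared by a two-sided exact permutation test, in which 3 against 3 libraries allow no p below 0.1. Read-count tests with edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 on the recovered reads were alternatives: edgeR called 4 miRNAs higher and 2 lower, and DESeq2 17 higher and 19 lower.

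The miRNAs named below follow a rule set in advance. It takes up to 12 per direction with the largest change among those past the threshold with a mean of at least 10 CPM and no overlap between groups, and fills short directions to 6 places with the smallest p. It adds the 10 most abundant miRNAs, up to 4 called and 2 abundant members of each list, and the 4 precursors with the smallest arm-ratio p. The other alternatives were pseudocounts of 0.5 and 5, no filter or a filter at 10 CPM, median centring, quantile normalization, rescaling without the 5 most abundant miRNAs, variance models without trend or with robust trend, the replicate number as a block, and leaving out each library in turn. Counting entries that share reads once was added after seeing the data. Among entries with at least 50 reads in every library, 15 pairs had recovered reads within 1% of each other in all 6 libraries. Of the 24 entries involved, 13 were left out.

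Positions are those of GRCm38 and are 1-based. A precursor was found in its annotation for 682 of the 685 entries. On simulated data made from these libraries with 200 changed miRNAs among 651 tested, the miRNA test recovered 61.5% of 1.5-fold, 78.5% of 2-fold and 98.5% of 4-fold changes, and 4.91% of its calls were unchanged miRNAs. With 60 changed precursors among 176, the arm-ratio test recovered 65.5% of 2-fold changes, and 2.56% of its calls were unchanged. Recovery after Benjamini-Hochberg adjustment depends on the share of items changed, and these simulated shares were large. In the real comparison limma called 5 of 666 miRNAs and 5 of 182 precursors, so the rates may overstate its sensitivity. Of 14 lists, the list raised 1.5-fold was found with a camera adjusted p of 2.91e-23 and 0 others were called. Simulated miRNAs varied independently, whereas the estimated correlation within the real lists ran from -0.09 to 0.53. The simulated result therefore does not show how the list test performs on correlated members.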

Results

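Small RNA sequencing measured 685 mature miRNAs in neuron-like N2a cells after retinoic acid (10 µM, over 96 h). The treated group received 5 µM RSL3 for 24 h. RSL3 inhibits GPX4, the glutathione peroxidase that reduces lipid peroxides, and induces the iron-dependent cell death called ferroptosis. The control group received DMSO, and each group had 3 libraries, so the comparison asks which miRNAs differ after RSL3 in these cells. The miRNA values used here hold no measure of cell death or lipid peroxidation, so how far ferroptosis had gone is not known. The recovered miRNA reads, summed over entries, ran from 4306460 to 6058006 per DMSO library and from 3406276 to 4989380 per RSL3 library. Across miRNAs, which are not independent replicates, Pearson's r of log2 values was 0.990 to 0.994 between libraries of a group and 0.987 to 0.993 between groups.

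Libraries from RSL3-treated cells had higher miR-5100, miR-467e-3p, miR-467c-3p and miR-215-5p and lower miR-615-3p than DMSO libraries. The rise of miR-5100 was 8.03-fold, from 9.50 ± 3.54 to 82.6 ± 23.5 CPM (SD, n = 3 per group), with a log2 fold change of 3.01 ± 0.25 (SE) and a limma adjusted p of 1.24e-05. The Sfmbt2-intron miRNAs miR-467e-3p and miR-467c-3p rose 2.16-fold and 2.13-fold, from 73.3 ± 22.2 to 159 ± 42.1 CPM and from 37.6 ± 5.40 to 81.5 ± 16.1 CPM, with limma adjusted p-values of 0.034 and 0.0088. The p53-responsive miR-215-5p rose 1.88-fold, from 10.5 ± 0.97 to 20.5 ± 2.04 CPM (limma adjusted p = 0.038). The level of miR-615-3p went to 0.676 of the control, from 268 ± 6.30 to 181 ± 2.01 CPM (log2 fold change -0.56 ± 0.11 SE, limma adjusted p = 0.034). In each of these miRNAs all 3 RSL3 libraries lay on the same side of all 3 DMSO libraries.

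**Figure D1:**
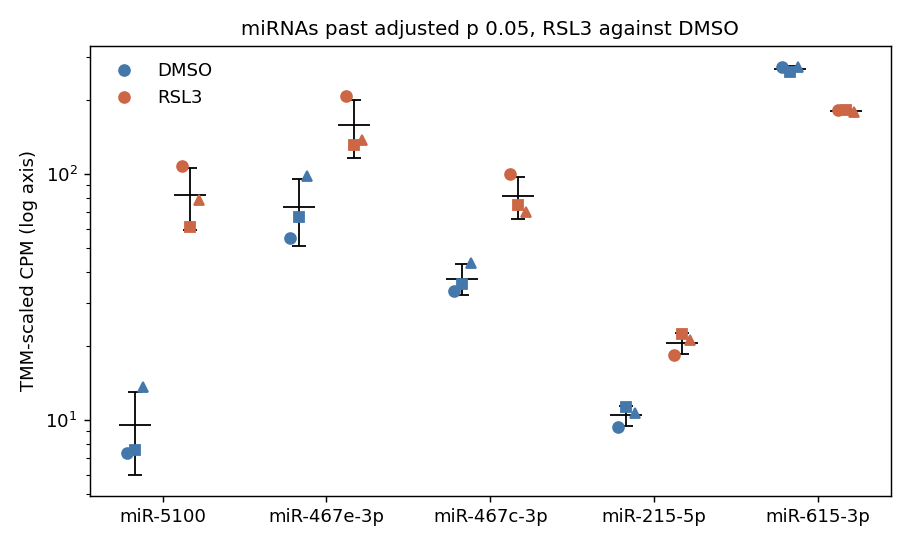
Levels of the 5 miRNAs that passed the threshold, in TMM-scaled CPM on a log axis, for DMSO (blue) and RSL3 (orange) libraries. Points are the 3 libraries of a group (circle, square and triangle for libraries 1, 2 and 3), and bars give the mean ± SD. The RSL3 libraries of miR-5100 sit between 61.2 and 108 CPM and its DMSO libraries between 7.37 and 13.6 CPM.

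The miR-5100 precursor lies on the plus strand of chromosome 11, from 60728663 to 60728726, in an intron of Mief2, a gene of mitochondrial dynamics. Its hairpin holds GTTCGAATC, a motif like the T arm of a tRNA. The miR-467c precursor (chromosome 2, 10473931 to 10474027) and the miR-467e precursor (chromosome 2, 10505721 to 10505807) lie on the plus strand in introns of Sfmbt2, a Polycomb-group gene whose introns hold a large miRNA cluster. The miR-467 and miR-669 families there have near-identical members, so the split of reads between them is uncertain. The miR-215 precursor is on the plus strand of chromosome 1, from 185313581 to 185313692, in an exon of the transcript 2010103J01Rik and antisense to Iars2. The miR-615 precursor lies on the plus strand of chromosome 15, from 103014910 to 103015001, in an intron of the homeobox gene Hoxc5.

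The next miRNAs by p did not pass in limma, while DESeq2 called each of those named here and edgeR called miR-669b-5p. On the higher side these were miR-325-3p (log2 fold change 0.77, adjusted p = 0.063) and miR-3535 (0.55, adjusted p = 0.072). On the lower side they were miR-669b-5p (-0.61), miR-669e-5p (-0.63), miR-6540-5p (-0.59), miR-669d-5p (-0.64) and miR-145a-5p (-0.52), with adjusted p-values of 0.056 to 0.063. Of the 666 miRNAs tested, 4 were called higher and 1 lower, and 3 of the 5 changed at least 2-fold. At an unadjusted p under 0.05 there were 59 higher and 56 lower miRNAs against 33.3 expected in all, and the groups did not overlap in 162 miRNAs (24.3%, where chance gives 10%). The counts depended on the scaling, tool and variance model: rescaling without the 5 most abundant miRNAs gave 4 higher and 12 lower, quantile normalization 3 and 1 (miR-215-5p was lost), a 10 CPM filter 4 and 3, edgeR 4 and 2, DESeq2 17 and 19, and limma without a trend 1 and 0. The higher and lower counts were 2 and 1 without DMSO library 1 (miR-467c-3p and miR-5100 of the 5 remained), 1 and 0 without DMSO library 2 (miR-5100), 4 and 0 without DMSO library 3 (miR-467c-3p, miR-467e-3p and miR-5100), 7 and 12 without RSL3 library 1, 14 and 5 without RSL3 library 2 (all 5 in both), and 2 and 0 without RSL3 library 3 (miR-467c-3p and miR-5100).

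Of the 10 most abundant miRNAs 0 passed in limma or edgeR. The X-linked miR-881-3p held 178630 ± 18004 CPM in DMSO and 239957 ± 61750 CPM in RSL3 libraries (log2 fold change 0.40, adjusted p = 0.32). The level of miR-7a-5p, a neuronal and endocrine miRNA, was 225023 ± 38694 CPM in DMSO and 181728 ± 26834 CPM in RSL3 libraries (-0.30, adjusted p = 0.41), and its relative miR-7b-5p had a log2 fold change of -0.27. The growth-associated miR-21a-5p had a log2 fold change of 0.30 (adjusted p = 0.29). The pair miR-467a-5p and miR-467b-5p, which share reads and cannot be separated, had a log2 fold change of 0.48 each (limma adjusted p = 0.072) and were the only ones of the 10 called in DESeq2, where they were higher, or at an unadjusted p under 0.05 in limma. The other abundant miRNAs, miR-465c-5p, miR-143-3p, miR-27b-3p and miR-470-5p, had log2 fold changes of 0.01, -0.00106, 0.05 and -0.08. The 10 most abundant entries took 65.8% to 68.9% of the signal of a library.

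Among lists tied to the treatment, the reported ferroptosis regulators had 26 negative and 15 positive log2 fold changes. Of their 41 tested members 0 passed in limma, edgeR or DESeq2, with 4 higher and 3 lower in limma at an unadjusted p under 0.05, and the list median was -0.09 (camera adjusted p = 0.44). Its most abundant members were miR-7a-5p and miR-7b-5p. Of 22 members of the list of Nrf2 or Keap1 regulators, which act on the antioxidant response, 0 passed in limma, with 3 higher and 0 lower unadjusted, and 1 passed in DESeq2 (miR-24-1-5p, higher). The list had a median of 0.09 and a camera adjusted p of 0.44. Camera and the median look for a shared direction, so members of these 2 lists that moved in opposite directions would cancel. Fry's mixed test, which allows opposite directions, gave an unadjusted p of 0.17 for this list and 0.052 for the ferroptosis regulators. Among 18 p53-responsive miRNAs miR-215-5p rose and 17 did not pass in limma. Both adjusted over the list alone and in DESeq2 over all miRNAs, miR-215-5p was higher and miR-145a-5p lower (952 ± 93.0 against 666 ± 78.4 CPM). The abundant members miR-143-3p and miR-192-5p had log2 fold changes of -0.00106 and 0.09, and the list's camera adjusted p was 0.58. In the hypoxia and inflammation list 12 of 16 members had a positive log2 fold change and 0 passed in limma over all miRNAs, with 2 higher and 1 lower unadjusted, a median of 0.14 and a camera adjusted p of 0.25. Adjusted over the list alone, and in DESeq2 over all miRNAs, miR-146a-5p, an inhibitor of NF-kB signalling, was higher (311 ± 50.6 against 444 ± 45.0 CPM). The summed level of this list was 38121 ± 2217 CPM in DMSO and 47009 ± 3427 CPM in RSL3 libraries (exact permutation p = 0.1, the smallest 3 against 3 can give), with miR-21a-5p and miR-9-5p (log2 fold change 0.39) as its most abundant members.

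Among lists of differentiation, growth and genomic clusters, the let-7 family, which restrains growth and marks differentiation, had 16 negative log2 fold changes among 19. In limma 0 passed, with 0 higher and 3 lower unadjusted, and the median was -0.17 (camera adjusted p = 0.25, or adjusted p = 0.70 with an estimated correlation). Summed let-7 was 32275 ± 2854 CPM in DMSO and 27493 ± 1641 CPM in RSL3 libraries (exact permutation p = 0.1), led by let-7c-5p (log2 fold change -0.35) and let-7f-5p (-0.04). The miR-17~92 clusters, which promote proliferation, had 0 of 20 members called in limma (0 higher and 1 lower unadjusted), with miR-25-3p at -0.12 and miR-92a-3p at -0.19 and a camera adjusted p of 0.41. The Dlk1-Dio3 imprinted cluster had 0 of 58 called in limma (4 higher and 2 lower unadjusted), with miR-127-3p at 0.10 and miR-381-3p at -0.04. Its median of -0.04 and mean of 0.03 differed in sign (camera adjusted p = 0.86, direction up). The neuron-enriched list had 0 of 38 called in limma (3 higher and 1 lower unadjusted). Its median was 0.02, negative under quantile normalization and under rescaling without the 5 most abundant miRNAs, and camera pointed down (adjusted p = 0.94). The retinoid-induced list had 0 of 28 called in limma (4 higher and 1 lower unadjusted) and 1 higher and 1 lower in DESeq2 (miR-24-1-5p and miR-152-5p), with miR-27b-3p at 0.05 and miR-99a-5p at 0.01. Its median of 0.04 turned negative under the same rescaling (camera adjusted p = 0.57).

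Entries that can stem from other RNA classes included miR-3535, which was higher adjusted over the list alone among 7 rRNA-like or snoRNA-like entries (373 ± 47.6 against 547 ± 78.3 CPM). Their summed level was 1394 ± 25.1 CPM in DMSO and 1754 ± 137 CPM in RSL3 libraries (exact permutation p = 0.1), with miR-1839-5p at a log2 fold change of 0.24 and a camera adjusted p of 0.34. Over all miRNAs 0 of the 7 passed in limma, with 3 higher and 0 lower unadjusted, while DESeq2 called miR-3535. The log2 fold changes of 6 entries were positive. In fry's directional test this list had an adjusted p of 0.46, which was 0.033 before adjustment. Among 15 mirtrons and other miRNAs made without Drosha, the nuclear processing enzyme, 0 passed in limma over all miRNAs (2 higher and 2 lower unadjusted). Adjusted over the list alone, and in DESeq2 over all miRNAs, miR-344-3p was lower (1447 ± 86.2 against 1051 ± 88.9 CPM). Their camera adjusted p was 0.57.

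Markers of other cell types gave 0 calls in limma and edgeR over all miRNAs. Among 12 endothelial, fibroblast and smooth muscle entries, miR-145a-5p was lower and miR-126a-3p higher (614 ± 29.8 against 802 ± 72.5 CPM) adjusted over the list alone and in DESeq2 over all miRNAs. That list had 1 member higher and 4 lower unadjusted, a median of -0.24 and a camera adjusted p of 0.25. The blood and immune list had 1 of 5 entries higher unadjusted, with miR-451a at 0.08, miR-486b-5p at 0.23 and a camera adjusted p of 0.44. The epithelial list had 0 of 5 unadjusted, with miR-203-3p at -0.07, miR-200b-3p at -0.02 and a camera adjusted p of 0.57. The glial list had 1 of 6 higher unadjusted, with miR-23a-3p at 0.38, miR-219a-2-3p at 0.05 and a camera adjusted p of 0.57. Its summed level was 894 ± 50.7 CPM in DMSO and 1112 ± 91.5 CPM in RSL3 libraries (exact permutation p = 0.1). Most of that sum was miR-23a-3p, at 685 ± 61.0 and 897 ± 115 CPM, while miR-219a-2-3p was at 139 ± 21.5 and 144 ± 27.8 CPM. Lists too small for camera were muscle, with 4 entries (miR-1a-3p at -0.41, miR-499-5p at -0.14, and miR-133a-3p lower adjusted over the list alone, 4.33 ± 1.24 against 1.85 ± 1.13 CPM), serum or liver, with 3 entries (miR-192-5p at 0.09, miR-451a at 0.08 and the liver miRNA miR-122-5p at 0.75, from 2.24 ± 1.14 to 4.48 ± 1.85 CPM), and pluripotent stem cells, with 1 entry (miR-295-3p at 0.27). At an unadjusted p under 0.05, 1 muscle entry was lower (miR-133a-3p), 1 serum or liver entry higher (miR-122-5p) and 0 pluripotent entries either. Of the names given here, miR-146a-5p, miR-126a-3p, miR-133a-3p, miR-122-5p, miR-24-1-5p and miR-152-5p lay outside the naming rule and were chosen after their values were seen. Over the 253 members of any list, limma and edgeR each called 1 and DESeq2 called 8. Of the 15 lists tested, 0 passed in camera with either correlation or in fry's directional test. An unadjusted p under 0.05 was reached by 2 lists in camera with the preset (let-7 at 0.017 and hypoxia and inflammation at 0.044). With an estimated correlation 0 lists reached it, and in directional fry 1 did (the rRNA-like or snoRNA-like entries). Fry's mixed test gave the p53-responsive list an unadjusted p of 0.0018, small enough to pass adjustment over the 15 lists. Under 0.05 but too large to pass were endothelial, fibroblast and smooth muscle (0.011), retinoid-induced (0.013), rRNA-like or snoRNA-like (0.024) and let-7 (0.038).

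**Figure D2:**
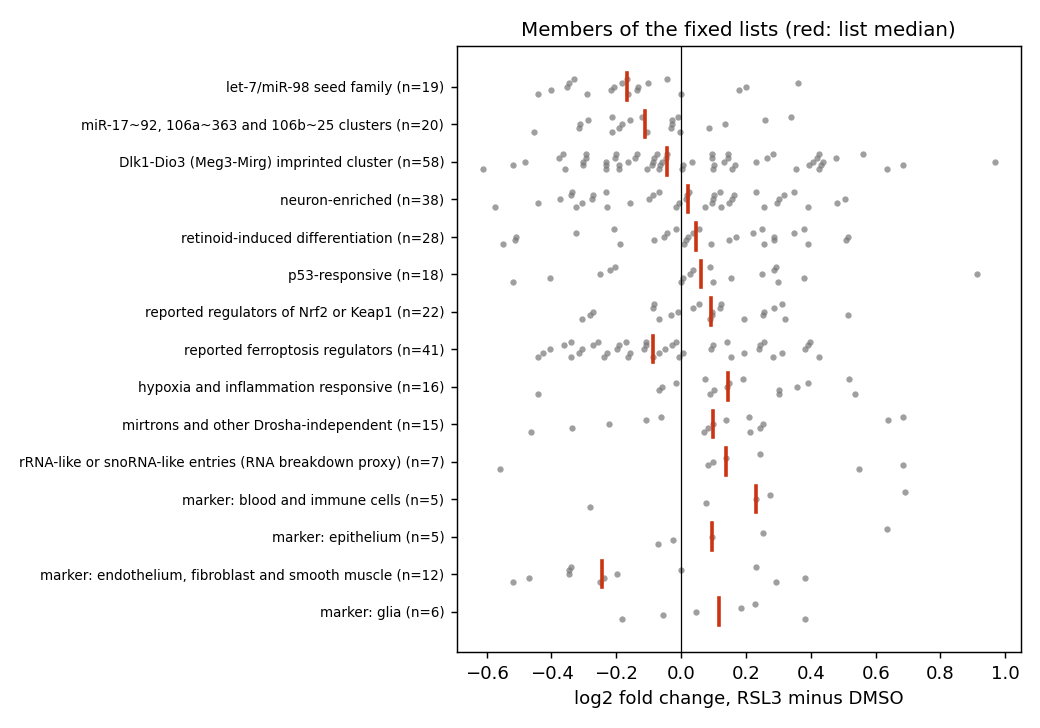
Log2 fold changes (RSL3 minus DMSO, on the log2(CPM + 1) scale) of the tested members of the 15 lists with at least 5 members. Each grey point is a miRNA, its vertical position within a list is arbitrary, red bars are list medians, and n is the number of members. The let-7 median lies at -0.17 and the hypoxia and inflammation median at 0.14, while 0 lists passed in camera.

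The 2 arms of a precursor were compared to ask whether the balance of its mature products shifted. It shifted toward the 3p arm in miR-467e, miR-669d, miR-325, miR-339 and miR-669h, of which miR-669h lay outside the naming rule and was chosen after its values were seen. For miR-467e the log2 ratio of 5p to 3p went from 3.09 ± 0.27 to 1.61 ± 0.31 (SD, n = 3 per group), a change of -1.48 ± 0.23 (SE, limma adjusted p = 0.016). Its 5p arm was at 616 ± 61.9 and 477 ± 40.7 CPM in DMSO and RSL3 libraries. The changes were -1.16 for miR-669d (limma adjusted p = 0.019), -1.03 for both miR-325 and miR-339 and -0.92 for miR-669h. The limma adjusted p was 0.048 for each of the last 3. The miR-669d ratio left out the separately listed miR-669d-2-3p, although the miR-669d 5p arm is assigned to both miR-669d precursors. In miR-325 the mean ratio was 0.71 ± 0.05 in DMSO and -0.33 ± 0.39 in RSL3 libraries, where the 5p arm stayed the higher one in library 1. The 3p arms of miR-669d and miR-669h were near the floor, at 1.43 ± 0.12 and 1.21 ± 0.33 CPM in DMSO and 2.60 ± 1.13 and 2.88 ± 0.59 CPM in RSL3 libraries.

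The miR-669d precursors (chromosome 2, 10468343 to 10468463 and 10471644 to 10471729) and the miR-669h precursor (chromosome 2, 10518155 to 10518279) lie in introns of Sfmbt2 on the plus strand, as does miR-467e. The miR-325 precursor (chromosome X, 105379082 to 105379179, minus strand) lies in an intron of 5330434G04Rik and the miR-339 precursor (chromosome 5, 139369650 to 139369745, minus strand) in an intron of 3110082I17Rik. Of 182 precursors, 5 passed toward 3p and 0 toward 5p in limma, the tool used for this ratio, with 25 and 15 at an unadjusted p under 0.05. The count was 2 with a pseudocount of 0.5 (miR-467e and miR-669d), 12 with a pseudocount of 5 (2 of them toward 5p, and miR-669h lost), and 5 toward 3p and 1 toward 5p with both arms at 10 CPM or more, a filter under which miR-669d and miR-669h were not tested. It was 3 without DMSO library 1 and 2 without RSL3 library 2 (miR-467e and miR-669d of the 5 remained in both), 0 without DMSO library 2, 1 without DMSO library 3 and 1 without RSL3 library 3 (miR-467e), and 4 without RSL3 library 1 (miR-325, miR-467e and miR-669d), so miR-339 and miR-669h were lost whichever library was left out.

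**Figure D3:**
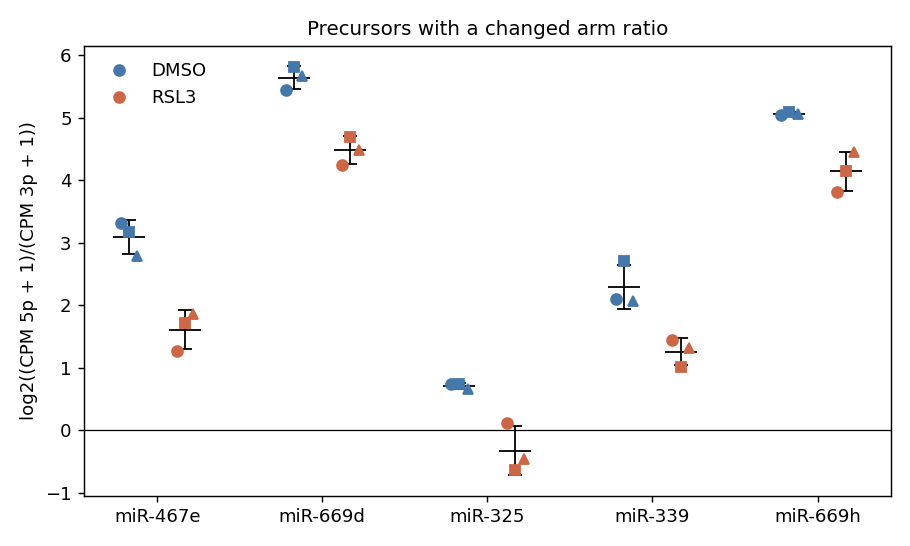
Log2 ratio of the 5p to the 3p arm, as log2((CPM of 5p + 1)/(CPM of 3p + 1)), for the 5 precursors whose ratio passed the threshold. Points are the 3 libraries of a group (circle, square and triangle for libraries 1, 2 and 3), and bars give the mean ± SD. The mean of miR-467e lies at 3.09 in DMSO (blue) and at 1.61 in RSL3 (orange).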

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

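Counting entries that share reads once was chosen after the data were seen, and the other settings before. The count of higher miRNAs, 4 as reported, was 1 without a variance trend, 17 in DESeq2, and 1 to 14 when a library was left out. The count of lower miRNAs, 1 as reported, was 3 with a 10 CPM filter, 12 after rescaling without the 5 most abundant miRNAs, 0 without a variance trend, 2 in edgeR, 19 in DESeq2 (which gave no adjusted p to 233 miRNAs), and 0 to 12 when a library was left out. The count of precursors with a changed arm ratio, 5 as reported, was 2 with a pseudocount of 0.5, 12 with a pseudocount of 5, and 0 to 4 when a library was left out. The cause of these changes was not tested. Samples with the same replicate number did not deviate together (correlations of -0.35, -0.33 and -0.19, and 0 of the samples correlated best with its own number). This gave no sign that the numbers pair the samples, but so few correlations cannot exclude it. With the replicate number as a block, 1 miRNA was higher, 0 lower and 2 arm ratios changed. Over the 19 alternatives, miR-5100 was called in 19 (log2 fold change 2.59 to 3.27), miR-467c-3p in 16, miR-467e-3p in 14, miR-615-3p in 13 and miR-215-5p in 12. Of 790 values of named miRNAs 739 kept their side of the threshold, 21 lost it, 30 gained it and 0 reversed. In 37 of those that kept it the sign of an uncalled change turned, as in 6 of 192 list values, where no call changed, and 11 of 126 summed levels, whose test cannot pass at this size. A read was worth 0.157 to 0.314 CPM, so miRNAs at a few CPM rest on few reads.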

Other observations

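The Sfmbt2 cluster was not among the lists fixed in advance, and it includes precursors already called for the arm ratio. Its comparison with precursors elsewhere therefore uses a set picked from these same data, although the prediction for it was written beforehand. The tests of miR-5100, the other tests of the Sfmbt2 arms and the sums below were chosen only after the results were seen. Introns of the Sfmbt2 gene, which spans 10370440 to 10595253 on chromosome 2, held precursors of 67 listed miRNAs. With entries that share reads counted once, the 5p arms of miR-669 had negative log2 fold changes in 11 of 11 entries (8 at an unadjusted p under 0.05, with 0 called in limma, 1 in edgeR and 4 in DESeq2), and their sum was 6404 ± 362.8 CPM in DMSO and 4843 ± 320 CPM in RSL3 libraries (SD, n = 3 per group, two-sided exact permutation p = 0.1, the smallest possible). The 5p arms of miR-467 had positive log2 fold changes in 3 of 4 entries (0 called in limma and edgeR and 2 in DESeq2, with 3 of the 4 at an unadjusted p under 0.05), with a sum of 31368 ± 987 CPM against 45399 ± 2592 CPM (exact permutation p = 0.1). With every entry counted, log2 fold changes of the 3p arms were positive in 11 of 13 entries of miR-669 (sum 3517 ± 278 against 3800 ± 275 CPM, 1 entry at an unadjusted p under 0.05) and in 5 of 5 of miR-467 (1265 ± 88.8 against 1783 ± 76.0 CPM, 4 entries), where miR-467c-3p and miR-467e-3p passed in limma. These 3p numbers count shared reads more than once (miR-669a-3p with miR-669o-3p, miR-467a-3p with miR-467d-3p). Partly shared reads among these near-identical members could not be flagged, so the 5p entries also do not count as independent. The difference between the miR-669 and miR-467 families was not tested. With every entry counted, the numbers of positive and negative signs on both arms were the same under median centring, quantile normalization and rescaling without the 5 most abundant miRNAs. The size was less stable for the miR-467 5p arms. Their median log2 fold change was 0.48 as reported, and 0.49, 0.26 and 0.43 under these 3 scalings.

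The X-linked cluster from Mir743 to Mir465 (chromosome X, 66776757 to 66839125), which includes miR-881-3p, took 31.3% ± 2.50 of the signal in DMSO and 35.9% ± 5.04 in RSL3 libraries. The Sfmbt2 cluster took 7.78% ± 0.43 in DMSO and 9.63% ± 0.11 in RSL3 libraries, with shared reads counted more than once. Of 13 genomic clusters with at least 5 tested miRNAs, 0 passed in camera. The smallest camera adjusted p was 0.65 with the preset and 0.92 with an estimated correlation. In the Sfmbt2 cluster 32 of 65 members were higher, so camera's test for a shared direction does not bear on its share of the signal. Over the 10 splits of the 6 libraries into 3 and 3, 1 split, the real one, gave as many as 5 called miRNAs, and the highest other gave 0. For the arm ratio 1 split, again the real one, gave 5, and the highest other gave 1. The splits are too few for a share under 0.05.

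The rise of miR-5100 was clear of the spread, with the lowest RSL3 library 4.51 times the highest DMSO library. Counting noise was argued against by edgeR, which models it (adjusted p = 1.03e-05, log2 fold change 3.12), and a general rise of entries that overlap other small RNAs by the median of 8 such entries, 0.12 (range -0.56 to 0.68), below the 95% interval of miR-5100, 2.47 to 3.54. Fragments of a single tRNA counted under this name remain open, since its hairpin is 1 of those of 9 entries that hold a motif like the T arm of a tRNA (here GTTCGAATC), and the only entry overlapping an annotated tRNA gene, miR-1983, had a log2 fold change of 0.0936. The motif alone does not mark a tRNA, since it also occurred in the hairpins of miR-322 and miR-434, which overlap no annotated tRNA gene. A response to RSL3, of the miRNA or of a tRNA fragment, also stays open and was not tested apart from the comparison itself.

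Among 30 precursors in Sfmbt2 introns with both arms tested, 24 (80%) had a change toward the 3p arm, 3 of them past the threshold. The median was -0.30 (95% bootstrap interval over precursors -0.49 to -0.20). Each precursor counted equally, so these values do not describe the balance of the cluster's reads. The precursors with its most abundant 5p arms, miR-467a and miR-467b, changed by 0.06 and 0.39, toward 5p (limma adjusted p = 0.88 and 0.49). A library-wide shift was argued against by the 152 precursors elsewhere, whose median was -0.0346 (-0.0912 to 0.0527) and whose mean ratio per library was 0.148 ± 0.0047 in DMSO and 0.137 ± 0.020 in RSL3 libraries. Arms near the detection floor were argued against by a median of -0.31 over 21 precursors with both arms at 10 CPM or more. Over 15 precursors with no arm flagged as sharing reads the median was -0.55, so the flagged pairs did not carry the shift. Reads counted under several names stay open otherwise. Entries under 50 reads in any library and partly shared reads could not be flagged. Whether the cluster's own change exceeds chance stays open, as does a response to RSL3, since its precursors are correlated: camera against the others gave p = 0.0867 with an estimated correlation of 0.12 and p = 8.25e-05 with the preset, and the cluster's mean ratio per library, 1.92 ± 0.10 in DMSO and 1.56 ± 0.09 in RSL3 libraries (SD, n = 3 per group), gave an exact permutation p of 0.1, the smallest possible.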
